A study of Homo sapiens with 17 samples.

How the data were processed

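RNA was sequenced from PC3 cells, an established human prostate cancer cell line, 7 days after infection with virus carrying a short hairpin RNA (shRNA). Per the labels' protocols, 2 lentiviral shRNAs against MED25 (A and B) and 2 retroviral shRNAs against ETV4 (A and B) were used. Each virus had its own control, which the labels' protocols give as a luciferase or control shRNA and the series design text as an empty vector. The 17 libraries comprised 3 for each shRNA, 3 for the lentiviral control and 2 for the retroviral control. Total RNA was extracted with a Qiagen RNeasy kit and libraries followed Illumina protocols, per the labels' protocols. No label says whether replicates came from separate cultures.

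Reads were aligned to hg19 with Novoalign 3.08.02, per the submitters' processing notes. The counting tool, its use of strand, the annotation release, the scaling between libraries and the test used by the authors are not given in the sources used here. Library-level values were not analysed here, so the depth of each library is unknown and no spread between replicates could be computed.

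The files used were 4 tables of the authors' own comparisons, 1 per shRNA, each naming a gene by Ensembl identifier and symbol. Per the file headers, the authors deposited for each gene a log2 ratio and an adjusted p, the second of which was treated as a score. The authors do not state the scale of this score in the sources used here. Its minimum lay just above 20 in every table, which would be an adjusted p of 0.01 if the scale were minus 10 times the log10. It was used only to rank and filter genes.

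The direction of each ratio was taken from the library numbers in the file headers, read as first over second, together with the sign of the targeted gene. The number shared by the tables of a target was read as the control, and it stood second for ETV4 and first for MED25. MED25 ratios were therefore turned round, so that every value below is knockdown over control on the log2 scale. With this reading, which the targeted genes helped to set, every listed gene was lower after knockdown, by at least 1.5-fold. Genes that rose were not analysed here, and a gene missing from a table cannot be called unchanged.

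Genes were matched by Ensembl identifier to GENCODE release 29, which is on a later genome build than hg19. That annotation served for gene types, chromosome names and neighbourhood, and 1350 of the 1400 genes in the union of the tables matched. No coordinates are given.

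Shared genes were counted for the 6 pairs of tables and set against the number for independent lists. The test was a one-sided Fisher's exact test at an assumed 12000 genes that could have been listed, since the number tested by the authors is not given in the sources used here. It takes each of these genes as equally likely to be listed, which was not checked. The 4 pairs of a MED25 with an ETV4 table were adjusted together by the Benjamini-Hochberg method. Both tables of a target share their control libraries, so part of their overlap may come from those. Simulating that share needs library-level values. Correlations of log2 ratios across shared genes used 100000 permutations and were adjusted over 6 pairs. Genes are not independent replicates.

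Before the data were examined, 29 gene lists, the named genes, the tests and most alternatives were fixed. A list with at least 3 members in a table was tested, which gave 22 tests adjusted together. Because that minimum depends on the count being tested, p-values were also adjusted over all 116 pairs of a list and a table, an alternative chosen after seeing the data. The planned test compared lower with higher genes and could not be run because every listed gene was lower. A one-sided hypergeometric test at the assumed 12000 genes was used instead, with all list members taken as measurable. It counts members as separate draws, so members regulated together would make its p-values too small. The planned tests of shared direction could not be run for the same reason. A list of 20 cytosolic aminoacyl-tRNA synthetases was added after the data were seen.

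The genes named are the targets, the 10 largest decreases per table, genes in all 4 tables, the 20 leading genes shared by the shRNAs of a target or by both targets, and up to 4 members per list. Genes named outside this rule are marked as chosen after their values were seen. Alternatives comprised a minimum absolute log2 ratio of 1, a score of at least 50, 8000 or 20000 assumed genes, protein-coding genes alone, and leaving out particular genes.

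Processed pseudogenes were compared with coding transcripts of the annotation by blastn 2.17.0+. Computations used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. The overlap test was tested on simulated independent lists of the sizes of MED25 shRNA A and ETV4 shRNA A. It called 5.44% of 5000 draws from 12000 genes at a threshold of 0.05, against 5.00% by exact calculation. For lists of the sizes of MED25 shRNA B and ETV4 shRNA B it called 3.90% against 3.32%. With exactly 20 shared genes planted, the count of shared genes was 20 in 100% of draws for both. This was fixed by the planting, so it checks the counting and not the power of the test.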

Results

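The data asked which genes depend on both MED25, a subunit of the Mediator complex, and ETV4, an ETS-family transcription factor, in PC3 prostate cancer cells. Each gene was depleted with 2 shRNAs and compared with control libraries of the same virus. The labels name a control shRNA for both viruses, while the series design text names an empty vector. All values below are log2 ratios of knockdown over control from the authors' deposited tables, which carry no error per gene. Every listed gene was lower after knockdown.

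The targeted transcripts were lower in all 4 comparisons. In the authors' deposited tables, MED25 (ENSG00000104973, chromosome 19) was at −0.96 with shRNA A, or 51.6% of control, and at −1.71 with shRNA B, or 30.5% of control. ETV4 (ENSG00000175832, chromosome 17) was at −1.94 with shRNA A, or 26.1% of control, and at −2.67 with shRNA B, or 15.8% of control, in the authors' deposited tables. ETV4 was listed in neither MED25 table, and MED25 in neither ETV4 table. The sign of the targeted genes was part of the basis for the direction of the ratios, so their decrease is not an independent check of it. Ranked by decrease, MED25 was number 218 of 786 genes with shRNA A and number 10 of 374 with shRNA B. For both targets, shRNA A left more of the targeted transcript but had the longer table. The numbers of genes were 786 against 374 for MED25 and 495 against 98 for ETV4. Length of table therefore did not follow loss of the targeted transcript. The differences between shRNAs were not tested, as library-level values were not analysed here.

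Histone genes were lower with both MED25 shRNAs, and amino acid stress genes were lower with MED25 shRNA A. The authors' deposited table for shRNA A listed 786 genes, with a median of −0.78, and 189 of them were lowered at least 2-fold. For shRNA B the authors' deposited table listed 374 genes, with a median of −0.77, and 75 were lowered at least 2-fold. Of the genes matched to the annotation, 91.2% were protein coding with shRNA A and 91.5% with shRNA B.

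Both MED25 shRNAs lowered 153 genes in common, against 24.5 for independent lists among the assumed 12000 genes (one-sided Fisher's exact p = 4.42e-85). Part of this excess may come from the shared lentiviral controls. Among these genes, the immediate early gene ARC was at −2.70 with shRNA A and −2.0 with shRNA B in the authors' deposited tables. The small heat shock protein CRYAB was at −2.25 and −2.12, and the inducible HSP70 gene HSPA6 at −1.66 and −1.81, in the authors' deposited tables. NGFR, the p75 neurotrophin receptor, was at −1.64 and −1.62, and the hedgehog-binding protein HHIP at −1.58 and −1.13, in the authors' deposited tables. Fibronectin (FN1), also listed with ETV4 shRNA B at −0.69, was at −1.18 and −1.62, the Notch ligand DLL4 at −1.43 and −1.08, and the repressor BHLHE40 at −1.21 and −1.35 in the authors' deposited tables. Across the 153 genes the log2 ratios gave Pearson r = 0.528 (permutation p = 1e-05, the smallest these permutations can give, adjusted p = 6e-05) and Spearman rho = 0.330 (adjusted p = 0.00048). The shared controls make this r positive with no common effect, and by how much was not estimated.

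Genes of unfolded protein and amino acid stress made up the list with 15 of 25 members lowered by MED25 shRNA A (exact hypergeometric adjusted p = 2.98e-11 at 12000 genes). Shared regulation of the members would make this p-value too small, and likewise that for ETV4 shRNA A below. In the authors' deposited table for this shRNA, the amino acid transporters SLC7A5 and SLC7A11 were at −1.77 and −1.58. The glutathione-degrading enzyme CHAC1 was at −1.65, the pseudokinase TRIB3 at −1.46 and the transcription factor ATF4 at −1.38 in the authors' deposited table. With shRNA B, 1 of the 25 was listed. Among genes listed for 1 MED25 shRNA alone, members made up 14 of 633 for A and 0 of 221 for B. This comparison was chosen after the result was seen. It did not pass the adjustment (two-sided Fisher's exact p = 0.0267, adjusted p = 0.187 over 7 tests).

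Histone genes were lowered by both MED25 shRNAs, with 15 of 24 list members for shRNA A (exact hypergeometric adjusted p = 2.54e-11) and 8 of 24 for shRNA B (adjusted p = 2.16e-06). HIST1H4C was at −1.55 and −0.63, and HIST1H2BF at −1.20 and −0.77, in the authors' deposited tables. Values of single histone genes are uncertain, since near-identical copies can share reads. The test counts these copies as separate draws, so shared reads or shared regulation would make its p-values too small. Both MED25 shRNAs were compared with the same lentiviral control libraries, so high histone values in those controls would appear with both. The 2 results are therefore not independent. Among genes lowered at least 2-fold, the histone list passed with shRNA A and had too few members to test with shRNA B.

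Genes induced by ERK signalling were lowered by MED25 shRNA B, with 5 of 23 members (exact hypergeometric adjusted p = 0.00267 over the 22 tests and 0.0141 over all 116). With shRNA A, 6 of 23 were listed (exact hypergeometric adjusted p = 0.0109 over 22 tests and 0.0577 over 116), which did not pass over all tests. IER2 was at −0.87 and −1.39 with the 2 MED25 shRNAs in the authors' deposited tables, and cyclin D1 (CCND1) at −0.94 with shRNA A. For AP-1 factors, 3 of 16 members were listed with shRNA B (exact hypergeometric adjusted p = 0.0342 over 22 tests and 0.180 over 116), with JUN at −1.41 and FOSL1 at −0.82 in the authors' deposited table. Of the epithelial-mesenchymal list, 4 of 27 members were listed with shRNA B (exact hypergeometric adjusted p = 0.0290 over 22 tests and 0.153 over 116). FN1 and SNAI1 are mesenchymal genes, while CLDN3 and KRT19, the last named after its value was seen, are epithelial ones. At 8000 assumed genes the ERK list with shRNA A (exact hypergeometric adjusted p = 0.0760), the AP-1 list (0.0992) and the epithelial-mesenchymal list (0.0992) did not pass over the 22 tests either. Among genes lowered at least 2-fold, these 3 lists had under 3 members with either MED25 shRNA.

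Other MED25 decreases included the acyltransferase AWAT2, which at −2.80 with shRNA A was the lowest value of that table, and galanin (GAL) at −1.78, in the authors' deposited table. With MED25 shRNA B they were at −0.92 and −0.79, and AWAT2 was at −0.64 with ETV4 shRNA A, in the authors' deposited tables. The authors' deposited table for shRNA B had the secreted endothelial product ESM1 at −1.78 and the argonaute gene AGO2, listed under the older symbol EIF2C2, at −1.12. Among ETS factors, ETS1 was at −0.67 and −0.79 with the 2 MED25 shRNAs, and ETV1 at −0.64 with shRNA A, in the authors' deposited tables. The Mediator gene MED22 was at −0.64 with MED25 shRNA A in the authors' deposited table.

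With MED25 shRNA A, lists that did not pass were AP-1 factors (3 of 16, exact hypergeometric adjusted p = 0.119), membrane transporters (4 of 26, 0.119), cell cycle genes (5 of 42, 0.168) and p53 targets (3 of 22, 0.199). The epithelial-mesenchymal list (3 of 27, 0.284), NF-kB genes (3 of 31, 0.348) and extracellular matrix genes (3 of 35, 0.405) did not pass either. With shRNA B, extracellular matrix genes (3 of 35, 0.122) did not pass. Among genes lowered at least 2-fold by shRNA A, membrane transporters passed with 4 of 26 members (exact hypergeometric adjusted p = 0.000679, or 0.0197 over all 116 tests), ABCG1, SLC1A5, ABCG2 and SLC38A1, the last named after its value was seen.

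PROKR1, KRT20, FLT1 and CD55 were lower with both ETV4 shRNAs, and amino acid stress genes were lower with ETV4 shRNA A. The authors' deposited table for shRNA A listed 495 genes, with a median of −0.79, and 115 of them were lowered at least 2-fold. For shRNA B the authors' deposited table listed 98 genes, with a median of −0.77, and 20 were lowered at least 2-fold. Protein-coding genes made up 89.4% and 92.9% of the matched genes.

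Both ETV4 shRNAs lowered 57 genes in common, against 4.04 for independent lists (one-sided Fisher's exact p = 7.38e-54 at 12000 genes). Part of this excess may come from the shared retroviral controls, of which there were 2 libraries. The prokineticin receptor PROKR1 was at −2.02 with shRNA A and −1.60 with shRNA B in the authors' deposited tables. Keratin 20 (KRT20) was at −2.16 and −1.10, and the VEGF receptor FLT1 at −1.15 and −1.29, in the authors' deposited tables. The complement inhibitor CD55 was at −1.51 and −1.07, the collagen gene COL4A6 at −1.16 and −0.94, and aldehyde oxidase AOX1 at −1.11 and −1.08 in the authors' deposited tables. The phospholipase gene PLD1 was at −2.03 and −0.68, the Fc receptor gene FCGR2A at −2.29 and −0.72, and the neuropeptide Y receptor NPY1R at −1.45 and −0.91 in the authors' deposited tables. TFEC, a basic helix-loop-helix factor, was at −1.14 and −1.16, and the arginine deiminase PADI1 at −1.60 and −1.15, in the authors' deposited tables. Of these genes, PROKR1 and CD55 were also listed with MED25 shRNA A, at −1.07 and −0.69, in the authors' deposited table. AOX1, PADI1 and COL4A6 were also listed with MED25 shRNA B, at −1.47, −0.88 and −0.65, in the authors' deposited table. Log2 ratios across the 57 genes gave Pearson r = 0.404 (permutation adjusted p = 0.00256) and Spearman rho = 0.380 (adjusted p = 0.00722). Here too the shared controls make r positive with no common effect, by an amount not estimated.

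The amino acid stress list was also lowered by ETV4 shRNA A, with 10 of 25 members (exact hypergeometric adjusted p = 1.79e-07 at 12000 genes). CHAC1 was at −2.11, SLC7A11 at −1.23, asparagine synthetase (ASNS) at −1.22 and TRIB3 at −1.13 in the authors' deposited table. With ETV4 shRNA B, 1 of the 25 was listed, SLC7A11, at −0.62 in the authors' deposited table. Of the members, 9 were in the tables of both MED25 shRNA A and ETV4 shRNA A.

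**Figure D1:**
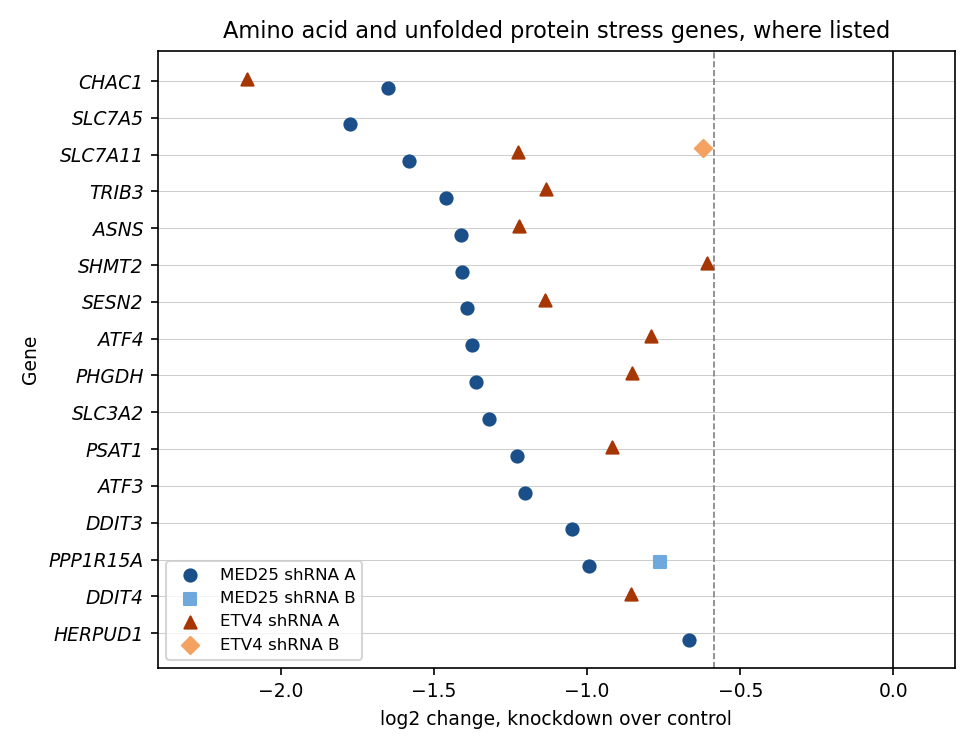
Log2 change of amino acid and unfolded protein stress genes, knockdown over control, as given in the authors' deposited tables. Each point is 1 gene in 1 table, and a missing point means not listed. The dashed line is the 1.5-fold minimum of the tables. MED25 shRNA A has 15 points and ETV4 shRNA A has 10, while each shRNA B has 1.

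With ETV4 shRNA A, the matrix protein gene SPARC was at −1.82, the collagenase MMP1 at −1.18 and the stromelysin MMP3 at −0.73 in the authors' deposited table. MMP3 was also at −1.50 with MED25 shRNA A in the authors' deposited table. Lists that did not pass with ETV4 shRNA A were membrane transporters (4 of 26, exact hypergeometric adjusted p = 0.0508), epithelial-mesenchymal genes (4 of 27, 0.0520), type I interferon genes (5 of 42, 0.0567) and NF-kB genes (4 of 31, 0.0683). ERK output genes (3 of 23, 0.113), of which ETV4 itself was 1, and histones (3 of 24, 0.117) did not pass either. No list had 3 members in the table of ETV4 shRNA B.

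The tables of MED25 and ETV4 shared more genes than independent lists in every pairing of shRNAs, and these pairs have no control library in common. As the sources differ on whether the controls carried an shRNA, these counts do not separate a response to any shRNA. The independent number takes each assumed gene as equally likely to be listed. Genes that pass the listing minimum more readily in any comparison would also raise these counts, which was not tested. MED25 shRNA A shared 112 genes with ETV4 shRNA A, against 32.4 for independent lists (one-sided Fisher's exact adjusted p = 2.82e-32 at 12000 genes). It shared 25 with ETV4 shRNA B, against 6.42 (exact adjusted p = 2.43e-09). MED25 shRNA B shared 47 genes with ETV4 shRNA A, against 15.4 (exact adjusted p = 8.83e-12), and 27 with ETV4 shRNA B, against 3.05 (adjusted p = 2.28e-18). In all, 143 genes were listed for at least 1 shRNA of each target.

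**Figure D2:**
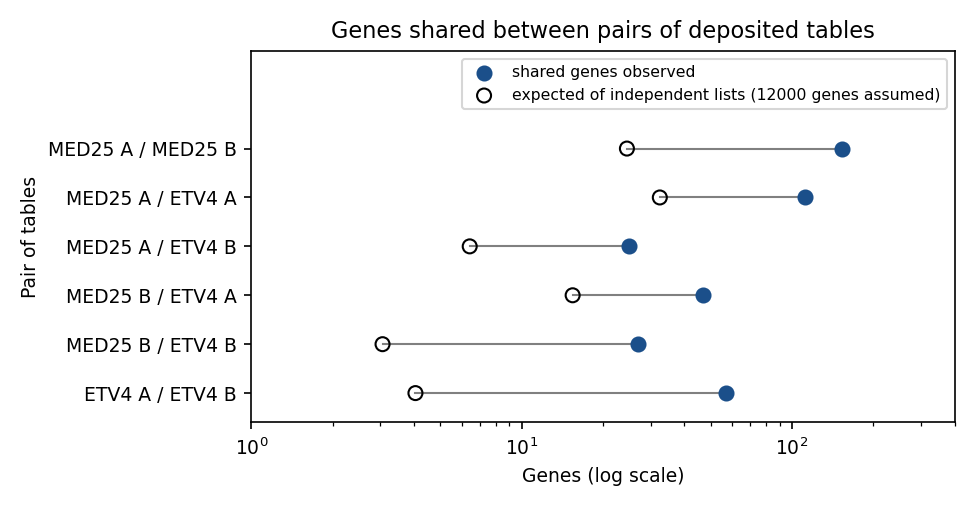
Genes shared by each of the 6 pairs of the authors' deposited tables (filled) and the number for independent lists at 12000 assumed genes (open), on a log axis. Observed counts run from 25 to 153 and lie above the independent value in every pair.

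Both shRNAs of both targets lowered 10 genes, against 0.727 for independent lists of 153 and 57 genes (one-sided Fisher's exact p = 2.18e-09 at 12000 genes). Values are given as MED25 A, MED25 B, ETV4 A and ETV4 B. The RNA-binding protein IGF2BP1 (ENSG00000159217, chromosome 17) was at −2.77, −1.88, −2.04 and −2.48 in the authors' deposited tables. The membrane scaffold ankyrin gene ANK2 (ENSG00000145362, chromosome 4) was at −1.77, −1.84, −1.34 and −1.50 in the authors' deposited tables. The potassium channel gene KCNK15 (ENSG00000124249, chromosome 20) was at −1.69, −1.74, −2.29 and −0.86 in the authors' deposited tables. Syndecan-1 (SDC1) was at −1.88, −1.73, −0.84 and −0.84, and the BMP antagonist noggin (NOG) at −1.57, −2.50, −0.79 and −0.61, in the authors' deposited tables. The Notch effector HEY1 was at −1.36, −1.27, −0.79 and −0.93, and the cytokine-signalling inhibitor SOCS2 at −0.94, −0.89, −1.59 and −1.21, in the authors' deposited tables. The small GTPase gene RASL11A was at −1.47, −1.29, −0.87 and −0.69 in the authors' deposited tables.

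The remaining genes of the 10 overlap on chromosome 7. The kinase gene CDK14 was at −0.96, −0.77, −0.86 and −0.64, and the antisense gene AC002456.2 at −2.31, −1.71, −1.85 and −1.56, in the authors' deposited tables. They lie on opposite strands, so their reads cannot be told apart if counting ignored strand, and these values are uncertain. The same holds for SOCS2 and its antisense gene RP11-887P2.1, which was at −0.77 with MED25 shRNA B and at −1.21 and −1.02 with the 2 ETV4 shRNAs in the authors' deposited tables.

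**Figure D3:**
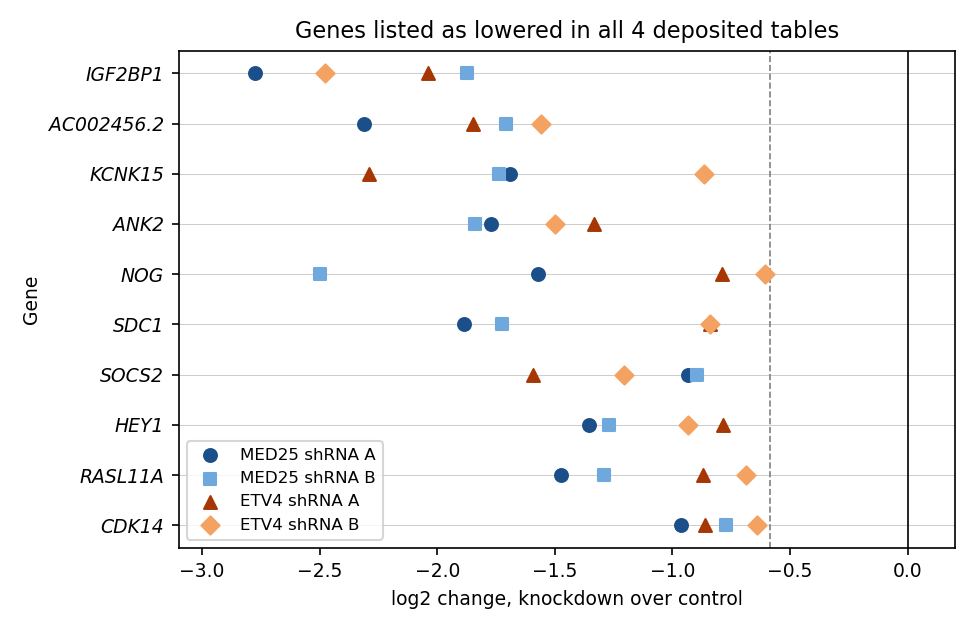
Log2 change, knockdown over control, of the 10 genes listed in all 4 of the authors' deposited tables. Each point is 1 table, and the dashed line is the 1.5-fold minimum. IGF2BP1 has the lowest mean, with values from −2.77 to −1.88, and CDK14 the highest, from −0.96 to −0.64.

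Size of change was correlated across shared genes for MED25 shRNA A with ETV4 shRNA A (Pearson r = 0.327, permutation adjusted p = 0.00255; Spearman rho = 0.280, adjusted p = 0.00722; 112 genes). For MED25 shRNA B with ETV4 shRNA B, r was 0.390 (adjusted p = 0.0495) and rho 0.280 (adjusted p = 0.235) over 27 genes. MED25 shRNA B with ETV4 shRNA A gave r = 0.111 (adjusted p = 0.460) and rho = 0.0276 (adjusted p = 0.851) over 47 genes, which did not pass. For MED25 shRNA A with ETV4 shRNA B, r was 0.609 (adjusted p = 0.00565) and rho 0.177 (adjusted p = 0.475) over 25 genes. Without the 2 genes farthest from the median, r fell to 0.0780 (permutation adjusted p = 0.729), so this relation rests on those genes.

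Other genes listed for both targets included the transcription factors CEBPB, at −1.06 with MED25 shRNA A and −0.98 with ETV4 shRNA A, and JDP2, at −1.45 and −1.07, in the authors' deposited tables. The cyclin-dependent kinase inhibitor CDKN2B was at −1.46 and −1.22, the peptide hormone UTS2 at −1.19 and −1.64, and the lipid transporter ABCG1 at −1.20 and −1.57 in the authors' deposited tables. None of CEBPB, JDP2, CDKN2B, UTS2 and ABCG1 was listed with shRNA B of either target, where the targeted transcript was lower. Their listing for both targets therefore rests on the A shRNAs, which also share the amino acid stress genes. ESM1 was at −1.78 with MED25 shRNA B, −0.87 with ETV4 shRNA A and −1.57 with ETV4 shRNA B in the authors' deposited tables.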

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

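All tests in this part were chosen after the result was seen, as was the synthetase list. With the stress list and synthetases combined, 26 of 633 genes listed for MED25 shRNA A alone were members, against 0 of 221 for B alone (two-sided Fisher's exact adjusted p = 0.00140 over 3 tests). The stress list by itself did not pass its own adjustment (Fisher's exact p = 0.0267, adjusted p = 0.187). Nor did the synthetases alone, with 12 of 633 against 0 of 221 (Fisher's exact p = 0.0434, adjusted p = 0.0651 over 3 tests). The difference therefore passed only with the lists pooled, and pooling added synthetases chosen after they were seen in that table. Of those, 13 of 20 were listed with MED25 shRNA A (exact hypergeometric p = 1.87e-11), such as GARS at −1.48 and AARS at −1.25 in the authors' deposited table, both chosen after their values were seen.

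Whether loss of MED25 transcript was the whole cause in MED25 shRNA A could not be decided. Of the 28 members listed for MED25 shRNA A, 2 were also listed for shRNA B, where MED25 was lower. Other genes of similar log2 change, in 5 equal groups, gave 7.46 expected (exact p = 0.0117). Without synthetases it was 1 of 15 against 4.48 (exact p = 0.0422). The members were flagged because most were listed for shRNA A and not for B, so low recurrence largely restates that pattern. The comparison was also changed after values were seen, and it matched genes by log2 change but not by score. Without matching, all 28 gave 2 against 151 of 758 other genes (Fisher's exact p = 0.141), and the 15 gave 1 (Fisher's exact p = 0.326). Genes at −1 or lower gave 0 of 20 against 54 of 169 (Fisher's exact p = 0.00114), or 0 of 13 without synthetases (Fisher's exact p = 0.0111). A longer A table cannot be told apart, since the list fixed beforehand gave an adjusted p of 0.187 (Fisher's exact test), nor can loss of ETV4 transcript, where 1 of 11 members recurred against 2.17 expected (exact p = 0.435). A sequence-specific effect of shRNA A, or a difference in culture or harvest, may also contribute and was not tested.

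Processed pseudogenes differed between the MED25 shRNAs, with 21 of 752 matched genes for A and 0 of 352 for B (two-sided Fisher's exact p = 0.000491). Of the 20 with a matching coding transcript, 8 had their parent gene in the same table, or 40.0% (exact 95% interval 19.1 to 63.9%), against 6.55% for any of the assumed 12000 genes. Some share a parent, and of 17 distinct parents 7 were listed, or 41.2% (exact 95% interval 18.4 to 67.1%). The 6.55% is a rate for any gene, whereas many parents were ribosomal protein genes, such as RPL10, RPL12 and RPS4X. Parents that fell together would also exceed that rate, so the excess alone cannot show shared reads. Reads shared with the parent may account for part of the pattern, for example for EEF1B2P3 at −0.86 and its parent EEF1B2 at −0.79 (99.0% identity) in the authors' deposited table. However, the closest copies, of RPL36A (100% identity), TCEA1 (99.7%) and EEF1A1 (99.4%), had parents that were not listed. Copies of RPS4X at 90.2% and 92.1% identity had a listed parent. In all, 10 of the 17 parents were not listed, so the rest stays open and no biological explanation was tested. All genes named here were chosen after their values were seen.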

How the results depend on the processing

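The score minimum of 50, the settings without stress genes or noncoding genes, the assumed gene numbers for list tests and the adjustment over all 116 list tests were chosen after the data were seen. Of 91 recomputed main values, 77 kept their direction and side of the threshold, or stayed within 1.5 times a count. Some of these 77 could not have moved. Leaving out MED25 and ETV4 took no gene from correlations of MED25 with ETV4 shRNAs, nor from the 10 genes listed in all 4 comparisons. Counting each symbol once removed no gene except with MED25 shRNA B, which went from 374 to 373. Each of the 48 recomputed overlaps stayed above independence, with ratios from 2.03 to 90 and one-sided Fisher's exact p at most 0.000237. For protein-coding genes alone the assumed 12000 genes were left unchanged, which tends to raise the ratio, so that setting is not a strict check.

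At an absolute log2 ratio of at least 1, the listed genes numbered 189 and 75 for MED25 shRNAs A and B and 115 and 20 for ETV4 shRNAs A and B. Genes in all 4 tables were then 3 (IGF2BP1, ANK2 and AC002456.2), and 4 gene-list tests passed instead of 8, of which 3 were among the 8. The added one was membrane transporters with MED25 shRNA A, and the 5 lost had under 3 members: histones, ERK, AP-1 and epithelial-mesenchymal with MED25 shRNA B, and ERK with A. At a score of at least 50 the tables held 509, 230, 300 and 61 genes. These counts drop by construction, as the filter removes genes. The correlation of MED25 shRNA A with ETV4 shRNA B was 0.0780 without the 2 farthest genes. Adjusted over all 116 list tests, 5 passed, since the 22 were admitted by their count of members. With 8000 assumed genes 5 list tests passed, and with 20000 genes 18 passed, since the assumed number sets the expected count.

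No paired analysis was possible because the tables hold no values per library, although the labels share replicate numbers. For that reason other normalizations, low-value filters, pseudocounts and leaving out replicates were not run. Direction tests could not be run, as every listed gene was lower. A score of at least 20 and the same direction removed no gene and say nothing. At an absolute log2 ratio of 1, correlations of ETV4 shRNA B with either MED25 shRNA had under 6 genes and gave no value. Depth is unknown.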

Other observations

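The neighbour test against random draws and the comparison of genes listed for both shRNAs of a target with genes listed for 1 were chosen after the result was seen. Histone symbols in all, beyond the fixed list, numbered 42 with MED25 shRNA A, 24 with MED25 shRNA B, 9 with ETV4 shRNA A and 0 with ETV4 shRNA B. Their medians were −0.91, −0.70 and −0.64 in the authors' deposited tables that listed any. The fixed lists for cholesterol and fatty acid synthesis, hypoxia and glycolysis, neuronal markers, and haematopoietic and stromal markers had 0 members in all 4 tables. Genes that rose were not analysed here.

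Interleukin 8, listed as IL8, was at −0.83 and −1.17 with the 2 MED25 shRNAs, and the chemokine CXCL2, also at −0.66 with ETV4 shRNA A, at −1.22 and −0.74, in the authors' deposited tables. The apoptosis inhibitor BIRC3 was at −0.71 and −0.98 with the 2 ETV4 shRNAs in the authors' deposited tables. The activin subunit INHBA was at −0.93 with MED25 shRNA A and at −0.78 and −0.83 with the 2 ETV4 shRNAs in the authors' deposited tables. The BMP target ID2 was at −1.09 and −1.03 with the 2 MED25 shRNAs in the authors' deposited tables.

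Genes listed for both targets lay near each other more often than random draws. Without histones, 135 such genes formed 17 pairs within 500 kb, against a mean of 7.85 (95% of draws 3 to 14) in 10000 draws from 1324 listed genes (one-sided permutation p = 0.00520), which argues against chance placement. Without pairs that overlap or lie within 5 kb, 11 pairs remained against 7.15 (95% of draws 2 to 13, permutation p = 0.115). Reads shared by overlapping genes, such as CDK14 with AC002456.2, SOCS2 with RP11-887P2.1 and PRSS23 with FZD4, the last pair chosen after the result was seen, may account for part. The 11 pairs lay within the range of the draws. They still include genes of overlapping pairs, such as CDK14 with STEAP1 and STEAP1 with AC002456.2. Joint regulation of neighbours such as PADI1 and PADI2, also chosen afterwards, stays open and was not tested.

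A further hypothesis was that genes lowered by both shRNAs of a target are more often listed for the other target. Of 57 genes listed for both ETV4 shRNAs, 30 were in a MED25 table (52.6%), against 113 of 479 listed for 1 (23.6%; two-sided Fisher's exact p = 1.08e-05), which is consistent with it. For MED25 the shares were 28 of 153 (18.3%) and 115 of 854 (13.5%; Fisher's exact p = 0.131), which leaves it undecided. Larger changes among genes listed for both shRNAs could also raise this share, and that was not tested.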
